A study of Mus musculus with 8 samples.

How the data were processed

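Poly-A messenger RNA was sequenced from 8 samples of BV2, a mouse microglial cell line. The cells were kept for 20 h without additions (Ctrl), with granzyme B at 500 ng/ml (GZMB), with 50 µl of amniotic fluid (AF), or with both (AF_GZMB), and each of the 4 groups held 2 samples. Per the submitters' processing notes, reads were called with CASAVA, trimmed with Trimmomatic 0.36, aligned to GRCm38/mm10 with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3. The strand setting of the counting and the annotation release were not given in the sources used here. The deposited table gives FPKM (fragments scaled by gene length and by the mapped total) as calculated by the authors, for 54532 genes. It also held 8 columns of per-sample values whose names match no sample of this series, and these were not used.

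The unit was checked on the values. FPKM multiplied by gene length was a whole multiple of a fixed step in every sample, with a largest distance of 0.000103 reads from a whole number and a tolerance of 0.001, so the number of reads behind each value could be worked out. The totals of these reads over the listed genes ran from 14692200 to 16481600 per sample, and the divisors behind the FPKM exceeded them by 0.922% to 5.24%. A gene without a read in a library was given a floor of 3 reads in that library. Floors cover counting error only, and reads without molecular identifiers are not independent molecules. In the file 27 gene symbols had been turned into dates and were restored from the gene identifiers, of which 54409 were found in GENCODE M21.

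The main test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a trend on log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 2 samples were tested, which left 11979 genes, 9958 of them protein-coding. All 4 groups entered 1 fit with a mean per group, which left 4 residual degrees of freedom beside 2.98 prior degrees of freedom. A gene was called when its p, adjusted by Benjamini and Hochberg over all genes tested in that comparison, was under 0.05. The 6 planned comparisons were GZMB with Ctrl, AF with Ctrl, AF_GZMB with AF, with Ctrl and with GZMB, and the difference of the granzyme B effects with and without amniotic fluid. The mean of both granzyme B effects was added after the data were seen. The fit, the list tests and the correction for GC content were tested on simulated data. Among 11979 simulated genes of which 200 were changed, the fit recovered 20% of the genes changed 1.5-fold in GZMB against Ctrl, 86.5% of those changed 2-fold and 95.5% of those changed 4-fold.

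The main test, the gene lists, the rule for naming genes and the first set of alternatives were set before the data were examined. The 32 lists covered type I interferon-stimulated genes, guanylate-binding proteins with immunity-related GTPases and other IFN-gamma-type genes, MHC class I and class II presentation, nucleic acid sensing, interferon receptors and signalling, NF-kB and inflammatory cytokines, chemokines, alternative activation, homeostatic microglia, disease-associated microglia, cholesterol synthesis, LXR targets, NRF2 and oxidative stress, ATF4 and the unfolded protein response, hypoxia and glycolysis, cell cycle, p53 targets, glucocorticoid targets, TGF-beta and matrix, granzymes with their serpin inhibitors and protease-activated receptors, and coagulation and complement. Markers of T and NK cells, epithelium, fibroblasts, erythroid cells, fetal liver and yolk sac, neutrophils, neurons, astrocytes and oligodendrocytes, and mitochondrially encoded transcripts as a measure of RNA quality, completed them. A tested member was present in 28 lists. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the lists. Counts of called members are given over all genes and adjusted over the list alone.

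Named genes followed a fixed rule. It took the 10 largest rises and falls among called genes with a mean of at least 2 FPKM in the higher group and no overlap between the samples, or the 5 with the smallest p where none passed. It added up to 4 members of each list by p, members that moved against their list, and a fixed set (Isg15, Ifit1, Ifit3, Rsad2, Irf7, Stat1, Usp18, Cxcl10, Ccl5, Ifnb1, Il1b, Tnf, Gzmb, Actb and Gapdh). Predicted genes and pseudogenes were passed over. The alternatives set beforehand were no filter on low values, a minimum of 5 FPKM, pseudocounts of 0.1 and 0.5, scaling by trimmed means of M values, quantile normalization, rescaling to TPM, no variance trend, the replicate number as a block, a minimum absolute log2 fold change of 1, only the 2 groups compared, and leaving out each library in turn. A planned test for tables of counts was not run because the values were FPKM. Alternatives added after the data were seen were limma voom on the recovered reads, protein-coding genes only, and a correction of each sample's trend on GC content and gene length with splines of 5 degrees of freedom. GC content was taken from the reference for 99.9% of the tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.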

Results

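Gene expression was compared in BV2 cells, a mouse line used as a model of microglia and macrophages, after 20 h with granzyme B, amniotic fluid, both or neither. Granzyme B is a serine protease of cytotoxic lymphocytes, and here it was added to the medium at 500 ng/ml. Each group held 2 samples, so every mean below is of n = 2, with the SD beside FPKM and the SE beside log2 fold changes. The reads on listed genes came to 14692200 (AF 1) to 16481600 (AF 2) per sample, and the other 6 samples lay between 15142700 and 16118700. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples. Changes are on the scale of log2(FPKM + 1), which understates those of genes with low FPKM. Where a library is left out below, the sample left alone in its group is assumed to vary like the other groups.

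The samples separated mainly by amniotic fluid. The first principal component carried 48.0% of the variance, with Ctrl at -24.8 and -22.5, GZMB at -15.6 and -16.5, and AF at 23.3 and 34.2. The AF_GZMB samples stood apart on it, at -5.35 and 27.4. The SD of the log2 difference between replicates was 0.316 in Ctrl, 0.309 in GZMB, 0.379 in AF and 0.460 in AF_GZMB. Mitochondrially encoded genes took 2.33% and 2.12% of the reads in Ctrl, 2.16% in each GZMB sample, 3.51% and 3.96% in AF, and 1.92% and 3.15% in AF_GZMB.

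The comparison of GZMB with Ctrl asked what extracellular granzyme B does to these cells on its own. Acod1, which encodes the macrophage enzyme that makes itaconate, rose from 1.59 ± 0.0149 to 9.21 ± 0.139 FPKM (log2 fold change 1.98 ± 0.12, limma adjusted p = 0.00689). Irf1, an interferon-induced transcription factor, rose from 5.10 ± 0.145 to 14.5 ± 0.606 FPKM (1.34 ± 0.11). C1qb, a chain of the complement protein C1q that microglia make, rose from 46.0 ± 3.10 to 96.1 ± 1.32 FPKM (1.05 ± 0.09). Ifitm3, an antiviral membrane protein induced by interferon, rose from 102 ± 4.58 to 193 ± 1.87 FPKM (0.91 ± 0.08). The limma adjusted p of each of these last 3 genes was 0.0312, and genes of the Ifitm family share sequence, so the part of Ifitm3 is uncertain. On GRCm38, Acod1 (ENSMUSG00000022126) lies on chromosome 14 from 103046977 to 103056573, Irf1 (ENSMUSG00000018899) on chromosome 11 from 53770014 to 53778374, C1qb (ENSMUSG00000036905) on chromosome 4 from 136880129 to 136886187, and Ifitm3 (ENSMUSG00000025492) on chromosome 7 from 141009586 to 141010770. In all, 4 genes rose and 0 fell by limma. At an unadjusted p under 0.05 there were 699 genes, of which 317 were higher and 382 lower, and voom called 15. The genes with the smallest p among those lower were Endog at -0.70 (adjusted p = 0.244), Cebpa at -0.56 (0.309), Mgst3 at -0.76, Hist1h1c at -0.47 and Pgp at -0.43 (0.341 each), and none passed. Without either Ctrl sample or either GZMB sample 0 genes were called, and without AF 1 or AF 2 there was 1.

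**Figure D1:**
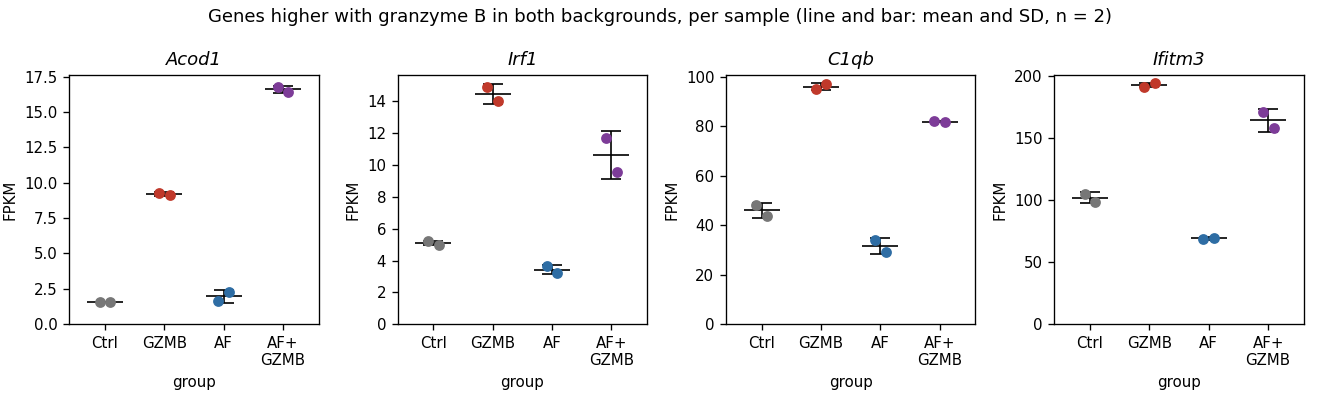
FPKM of Acod1, Irf1, C1qb and Ifitm3 in each of the 8 samples by group (points), with the mean (line) and SD (bar) of n = 2. Both samples with granzyme B lay above both samples without it, in medium alone and in amniotic fluid.

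Few members of the interferon-related lists were called singly, although most were higher. Of the 41 tested type I interferon-stimulated genes, the antiviral programme driven by IFN-alpha and IFN-beta, 39 were higher with GZMB and the median change was 0.33. None was called over all genes and 15 rose when adjusted over the list alone, with a camera adjusted p of 8.48e-21. Its members with the smallest p were Parp14 at 0.91 (limma adjusted p = 0.0821 over all genes), Oas3 at 0.54 (0.266), Lgals3bp at 0.70 (0.295) and Rsad2 at 0.72 (0.341). Guanylate-binding proteins and other IFN-gamma-type genes, which restrict pathogens inside macrophages, were higher in 11 of 11 tested members with a median of 0.68. Of these 2 rose over all genes (Acod1 and Irf1) and 8 adjusted over the list alone, with a camera adjusted p of 1.31e-19. Gbp3 was at 1.71 (0.0727) and Gbp2 at 1.56 (0.118), from 0.191 ± 0.0999 to 2.52 ± 0.547 FPKM. MHC class I presentation, which loads peptides for cytotoxic T cells, was higher in 18 of 18 tested members with a median of 0.67. Tapbpl at 1.06 and Nlrc5 at 0.93 (0.0558 each), Tapbp at 0.64 (0.0778) and Tap1 at 1.00 (0.111) led it. None of its members was called over all genes, 14 rose adjusted over the list alone, and the camera adjusted p was 5.49e-28 at the preset correlation and 0.0545 with an estimated correlation. In both comparisons of granzyme B, without and with amniotic fluid, the type I and IFN-gamma-type lists held with an estimated correlation (0.00860 each here) and the MHC class I list did not. After the GC and length correction, added after the data were seen, the MHC class I list passed as well. Its camera adjusted p with an estimated correlation was then 0.00337 for GZMB against Ctrl and 0.00589 for AF_GZMB against AF.

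**Figure D2:**
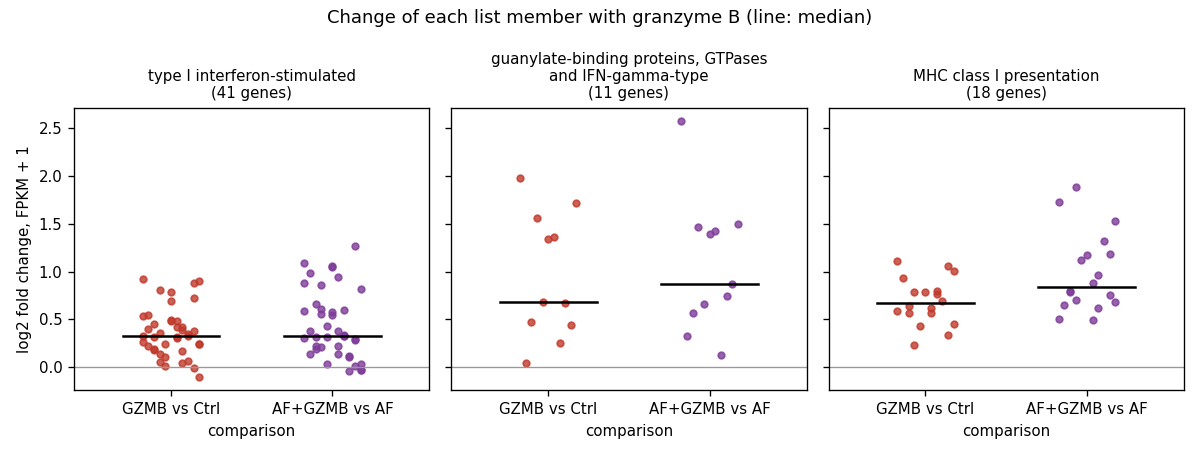
Log2 fold change (FPKM + 1) of each member (points) of 3 interferon-related lists, with the list median (line), for GZMB against Ctrl and AF_GZMB against AF. The medians were 0.33 and 0.33 for 41 type I genes, 0.68 and 0.87 for 11 IFN-gamma-type genes, and 0.67 and 0.84 for 18 MHC class I genes.

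Several classic interferon and inflammatory genes did not pass with GZMB alone. Isg15 was at 0.88 ± 0.38 (limma adjusted p = 0.862), Stat1 at 0.92 (0.404), Irf7 at 0.49 (0.834), Ifit1 at 0.36 (0.901) and Usp18 at -0.01 (0.999). Tnf was at 0.26 (0.929), Ccl4 at 0.61 (0.459) and Ptgs2 at 0.54 (0.454). The other C1q chains, C1qa at 1.27 (0.670) and C1qc at 0.69 (0.459), did not pass either. Homeostatic microglia genes had 1 rise over all 15 tested (C1qb), 4 rises and 1 fall adjusted over the list alone, and a camera adjusted p of 0.0187, which was 0.229 with an estimated correlation. For chemokines the camera adjusted p was 0.0572, for nucleic acid sensing 0.0898 (fry 0.0398), for MHC class II 0.125, for NF-kB and inflammatory cytokines 0.440, and for interferon receptors 0.530. In 3 lists far from passing the signs differed: alternative activation had a median of -0.00 and a mean of 0.07, cholesterol synthesis had -0.01 and 0.01, and hypoxia and glycolysis had -0.06 and 0.02 with a camera direction downwards. Csf1 was at 0.47 (0.214) and Serpinb9, an inhibitor of granzyme B, at 0.53 (0.587). Actb was at -0.16 (0.884). Gapdh was at 1.83 (0.343), with 26.3 ± 15.2 FPKM against 6.04 ± 0.315, and is uncertain because its many copies in the genome share reads.

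The comparison of AF_GZMB with AF asked what granzyme B does in the presence of amniotic fluid. Acod1 rose from 1.97 ± 0.449 to 16.6 ± 0.254 FPKM (log2 fold change 2.57 ± 0.12, limma adjusted p = 0.00114), and it was called under all 20 alternatives that kept the 4 groups in 1 fit, but not with only the 2 groups compared (0.329). Tap1, which pumps peptides to MHC class I, rose from 4.57 ± 0.933 to 15.0 ± 1.00 FPKM (1.53 ± 0.13, 0.0168). Irf1 rose by 1.39 ± 0.11 (0.0148), C1qb by 1.35 ± 0.09 (0.00760) and Ifitm3 by 1.24 ± 0.08 (0.00608). Tapbpl at 1.19 and Tapbp at 0.80 (0.0215 each), H2-T23 at 1.17 and Ifi204 at 0.98 (0.0350 each), Lgals3bp at 1.06 (0.0425) and Asb11 at 0.87 (0.0350) rose as well. Under the same 20 alternatives the call of Lgals3bp held in 8, Asb11 in 9, H2-T23 in 10, Ifi204 in 11 and Tapbp in 12. Those of Tap1 and Tapbpl held in 13 each, Irf1 in 14, Ifitm3 in 17 and C1qb in 18. Slc15a3, at 0.81 (0.0215), was the remaining called gene and was named after its value was seen. H2-T23 is uncertain because MHC class I genes share sequence. In all, 12 genes rose and 0 fell by limma, 1365 had an unadjusted p under 0.05 (837 higher and 528 lower), and voom called 40. All 12 were higher with granzyme B in medium alone too. Among genes lower but not called were Hist1h3i at -1.57 (0.0707), mt-Tp at -1.70 (0.121) and Aldh6a1 at -0.62 (0.147). The count was 4 without Ctrl 1, 4 without Ctrl 2, 1 without GZMB 1, 5 without GZMB 2, 4 without AF 1 and 1 without AF 2. It was 1094 without AF_GZMB 2, which leaves the AF_GZMB sample with the lower share of mitochondrial reads, and 9 without AF_GZMB 1.

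The same 3 lists were higher with granzyme B in amniotic fluid. Of 41 type I genes 38 were higher (median 0.33), 2 rose over all genes (Ifi204 and Lgals3bp) and 18 adjusted over the list alone, with a camera adjusted p of 2.28e-14, or 0.0152 with an estimated correlation. Of 11 IFN-gamma-type genes 11 were higher (median 0.87), 2 rose over all genes and 10 adjusted over the list alone, with a camera adjusted p of 1.38e-14, or 0.0152 with an estimated correlation. Of 18 MHC class I genes 18 were higher (median 0.84), 4 rose over all genes and 17 adjusted over the list alone, with a camera adjusted p of 1.36e-24, or 0.0688 with an estimated correlation. Parp14 was at 0.82 (limma adjusted p = 0.0756), Stat2 at 0.60 (0.121), Irgm1 at 0.74 (0.0756), Isg15 at 1.26 (0.331), Irf7 at 0.95 (0.192), Stat1 at 0.88 (0.213) and Rsad2 at 0.29 (0.436). The 12 mitochondrially encoded transcripts were all lower, with a median of -0.69. None was called over all genes and 9 fell adjusted over the list alone, with a camera adjusted p of 3.76e-07, or 0.426 with an estimated correlation. Without AF_GZMB 1, whose mitochondrial share of 1.92% was the lowest of all samples, the median of that list was -0.29 (camera adjusted p = 0.000119, or 0.616 with an estimated correlation). Chemokines (camera adjusted p = 0.00556, with Ccl4 at 0.70, Ccl2 at 0.65 and Cxcl14 at 0.55), NF-kB and inflammatory cytokines (0.0187, with Cd14 at 0.47) and MHC class II (0.0410, with Ctss at 0.53) had no called member, and with an estimated correlation their adjusted p was 0.409, 0.409 and 0.426. Erythroid markers, with Hba-a1 at 1.06 (limma adjusted p = 0.0756) and Hbb-bs at 0.65 (0.213), had a camera adjusted p of 0.0150, or 0.286 with an estimated correlation. LXR targets had a median of -0.03 and a mean of 0.01, and the granzyme and serpin list had 0.06 and -0.02, far from passing.

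Averaged over both backgrounds, which was a comparison added after the data were seen, granzyme B raised 32 genes and lowered 1. The rises named by the rule were Acod1 at 2.28 ± 0.08 (limma adjusted p = 0.000243), Gbp3 at 1.61 (0.0113), Gbp2 at 1.51 (0.0132), Psmb9 at 1.42 (0.0168), Gbp7 at 1.39 (0.0279), Irf1 at 1.37 (0.00159), Tap1 at 1.26 (0.00477), C1qb at 1.20 (0.00159), Tapbpl at 1.12 (0.00437) and Ifitm3 at 1.07 (0.00149). Psmb9 is a subunit of the immunoproteasome, which cuts peptides for MHC class I. C1qc (0.88, 0.0330), Parp14 (0.86, 0.0116), Lgals3bp (0.88, 0.0132), Nlrc5 (0.79, 0.0116), Ifi204 (0.76, 0.0132) and Csf1 (0.51, 0.0149) also rose, whereas Ccl4 at 0.65 (0.0704) and Stat1 at 0.90 (0.0718) did not pass. The fall was Mir3473d, which had 0 to 6 reads per library and is uncertain, as the strand setting was not given. Of the 33 called genes, 20 were members of the 3 interferon-related lists. Higher in both backgrounds were 37 of 41 type I, 11 of 11 IFN-gamma-type and 18 of 18 MHC class I genes. Over all genes 3, 7 and 10 of them rose, and 24, 10 and 18 adjusted over the list alone. Their camera adjusted p was 1.85e-32, 1.38e-26 and 6.11e-43, and all 3 held with an estimated correlation (0.00386, 0.00467 and 0.0246). Chemokines (0.000137, or 0.231 with an estimated correlation), NF-kB and inflammatory cytokines (0.00339, or 0.268), MHC class II (0.00339, or 0.289), nucleic acid sensing (0.00528, or 0.180), homeostatic microglia (0.0110, or 0.180) and mitochondrial transcripts, which were lower (1.99e-07, or 0.385), did not. Without 1 library the count was 12 (Ctrl 1), 6 (Ctrl 2), 4 (GZMB 1), 8 (GZMB 2), 14 (AF 1), 6 (AF 2), 37 (AF_GZMB 1) and 91 (AF_GZMB 2).

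Whether the granzyme B effect differed with amniotic fluid was tested as an interaction. Acod1 was higher by 0.59 ± 0.16 with the fluid (limma adjusted p = 0.452), Tap1 by 0.53 ± 0.18 and Ifitm3 by 0.32 ± 0.11 (0.452 each), and Irf1 by 0.05 ± 0.16 (0.905). No gene was called by limma, 1314 had an unadjusted p under 0.05, and voom called 0. The smallest adjusted p was 0.385, shared by Map1lc3a at 0.96, Zfp580 at 0.86, Amdhd2 at 0.70, Rpp25l at 1.79 and Rilpl2 at 0.79, and on the lower side by Hist1h3i at -1.75. The type I list had a median difference of 0.05 (camera adjusted p = 0.761), which was -0.07 after rescaling to TPM, and the IFN-gamma-type list 0.07 (0.585). The MHC class I list had a median difference of 0.27 (0.0286, or 0.798 with an estimated correlation), with 14 of 18 members on the higher side. The mitochondrial list had a median difference of -0.59 (0.0119, or 0.798 with an estimated correlation). The erythroid list had a camera adjusted p of 0.113 and a fry adjusted p of 0.000128, on 3 genes without a read outside amniotic fluid, so it restates their change between AF_GZMB and AF. Without AF 1 there was 1 called gene, without AF_GZMB 1 there were 2, and without AF_GZMB 2 there were 622.

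The comparison of AF with Ctrl asked what amniotic fluid does on its own, and the genes with the largest rises were those of adult haemoglobin. Hbb-bs (chromosome 7, 103826534 to 103828096) and Hba-a1 (chromosome 11, 32283511 to 32284465) had 14.7 ± 2.62 and 7.96 ± 1.32 FPKM in AF and no read in Ctrl. Against a floor of 3 reads per library they were at least 59.6-fold and 34.2-fold higher (limma adjusted p = 0.000188 and 0.000703). Globin reads numbered 303 and 291 in AF, 556 and 562 in AF_GZMB and 0 in each of the other 4 libraries. The paralogs Hba-a2 and Hbb-bt share sequence with them, so the split between copies is uncertain. Id3, a target of BMP and TGF-beta signals, fell from 18.0 ± 0.0218 to 1.33 ± 0.0751 FPKM (-3.03 ± 0.21, 0.00239), and Apoe, the main lipid carrier of microglia, from 370 ± 9.56 to 65.1 ± 15.5 FPKM (-2.51 ± 0.35, 0.00941). Skil, an inhibitor of SMAD signalling that TGF-beta induces, rose from 2.69 ± 0.239 FPKM by 1.82 ± 0.10 (0.00125), and the plasminogen activator gene Plau from 164 ± 8.47 to 365 ± 6.43 FPKM (1.15 ± 0.08, 0.00239). Cox8a fell by 2.50 (0.0147), Rnaseh2c by 2.66 (0.0167), Pfdn6 by 2.25 (0.0257), Edf1 by 2.18 (0.0265), Mien1 by 2.07 (0.0179) and Lamtor2 by 2.03 (0.0288). Mitochondrial tRNA genes rose with the share of mitochondrial reads, from 2.33% and 2.12% to 3.51% and 3.96%: mt-Tp at 2.57 (0.00733), mt-Tc at 2.29 (0.0274), mt-Tr at 2.15 (0.0440), mt-Tw at 2.09 (0.0274) and mt-Tn at 1.97 (0.0238). Rps27rt at 2.25 (0.00882) shares sequence with Rps27, and Snora30 at 2.23 (0.00858), Mir6929, Mir7052 and Mir130b are short genes with at most 16 reads per library, so all 5 are uncertain.

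**Figure D3:**
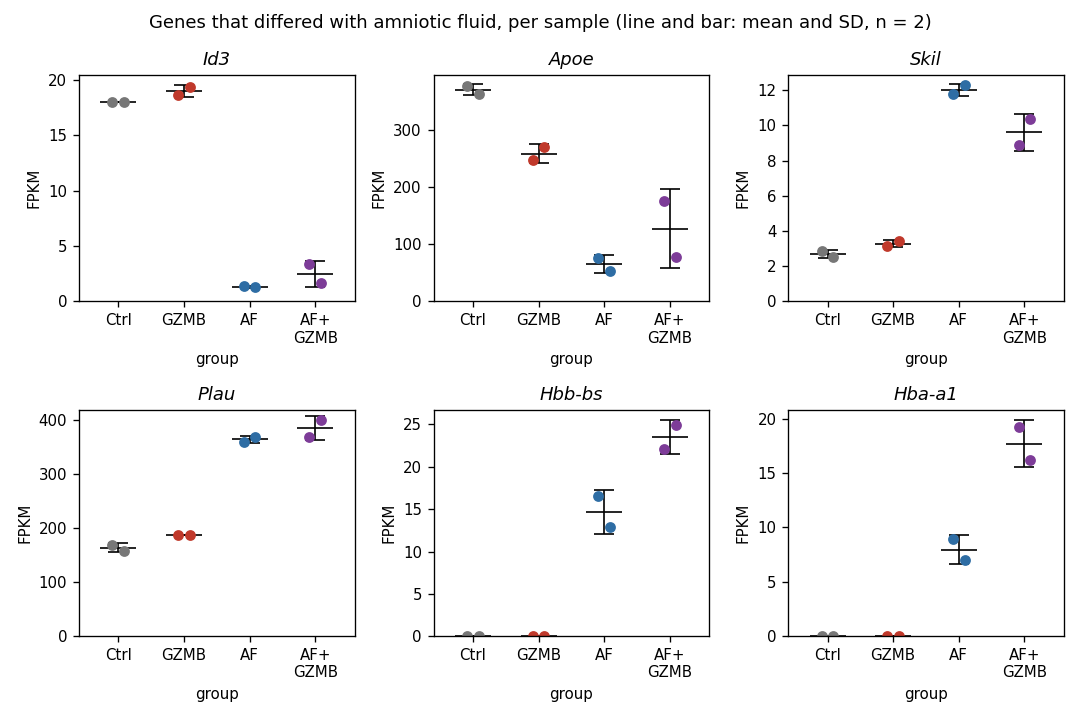
FPKM of Id3, Apoe, Skil, Plau, Hbb-bs and Hba-a1 in each of the 8 samples by group (points), with the mean (line) and SD (bar) of n = 2. Hbb-bs and Hba-a1 had 0 reads in the 4 samples without amniotic fluid.

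In all, 1757 genes rose and 2002 fell with AF by limma, of which 99 rose and 323 fell at least 2-fold. These were 3759 of the 11979 genes tested. With so large a share called, a list can hold several calls without standing out from the other genes. The count depended on single libraries: it was 12 without Ctrl 1, 41 without Ctrl 2, 1888 without GZMB 1, 1854 without GZMB 2, 739 without AF 1 and 23 without AF 2, and it stayed above 3759, at 4990, without either AF_GZMB sample. Hbb-bs and Hba-a1 were called under all 20 alternatives that kept the 4 groups in 1 fit and Id3 under 19, with an adjusted p up to 0.0574, and all 3 with only the 2 groups compared (0.00630 each). The changes also followed the GC content of the genes. Across 9950 protein-coding genes, which are not independent replicates, the Spearman correlation of the AF change with GC content was -0.655 and with gene length 0.424. With GC content the correlation was -0.422 for GZMB against Ctrl and 0.492 for AF_GZMB against AF. After a correction for GC content and gene length, added after the data were seen, 1509 genes were called with AF, 724 up and 785 down, and 1163 of them were among the 3759. Id3 (-2.60, 0.00137), Apoe (-1.98, 0.0130), Hbb-bs and Hba-a1 were still called. The calls of mt-Tc (from 2.29 ± 0.57 to 1.61 ± 0.45, 0.0593), Edf1 (from -2.18 ± 0.53 to -1.68 ± 0.45, 0.0554) and Lamtor2 (from -2.03 ± 0.52 to -1.55 ± 0.44, 0.0615) ended although their changes stayed large, as did those of mt-Tr (1.47, 0.102), mt-Tw (1.49, 0.0617) and mt-Tn (1.28, 0.0506), and of Mir6929, Mir7052 and Mir130b.

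**Figure D4:**
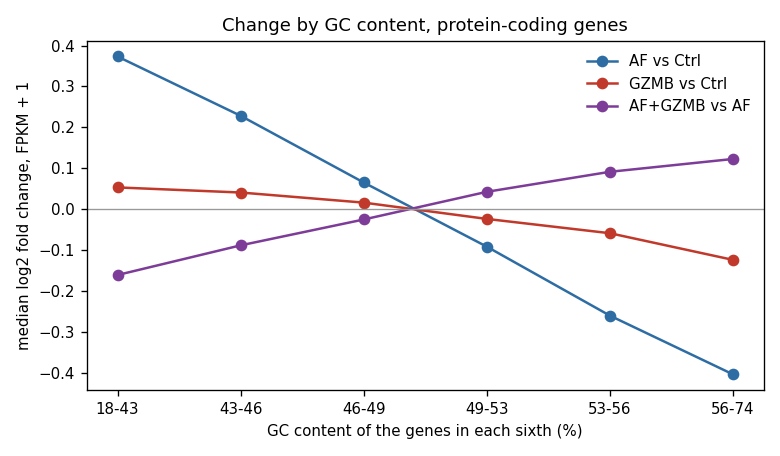
Median log2 fold change (FPKM + 1) of protein-coding genes in sixths by GC content (%), for AF against Ctrl, GZMB against Ctrl and AF_GZMB against AF. With AF the medians ran from 0.37 in the sixth with the lowest GC content to -0.40 in the highest.

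Among the calls with AF most type I genes rose and most MHC class I genes fell, and the difference between the lists was not tested. By camera before the GC and length correction, these lists passed at the preset correlation and the others given here did not. The adjusted p was 0.981 for IFN-gamma-type genes, 0.291 for MHC class II and 0.852 for nucleic acid sensing. It was 0.594 for interferon receptors, 0.238 for NF-kB, 0.657 for chemokines and 0.807 for alternative activation. Among type I genes 11 rose and 2 fell over all genes, and as many adjusted over the list alone, among them Eif2ak2 at 0.67 (limma adjusted p = 0.00882), Samd9l at 0.84 (0.0119), Rsad2 at 0.81 (0.0132) and Ddx58, the RNA sensor RIG-I, at 0.74 (0.0161). The camera adjusted p was 0.00867, or 0.329 with an estimated correlation, and after the GC and length correction 11 rose and 0 fell (0.00549, or 0.211). These 4 were then at 0.43 (0.0222), 0.44 (0.0310), 0.61 (0.0230) and 0.57 (0.0326). MHC class I genes fell in 10 and rose in 2 of 18 over all genes, and 13 fell and 2 rose adjusted over the list alone, with H2-D1 at -0.88 (0.00882) and H2-K1 at -0.53 (0.0141), whose sequences overlap, Psmb10 at -0.82 (0.0160) and Psmb8 at -0.85 (0.0201). The camera adjusted p was 0.0111, or 0.741 with an estimated correlation, and it was 0.197 after the GC and length correction, with a median of -0.15, 1 rise and 3 falls. The falls were H2-D1 at -0.48 (0.0124), Psmb10 at -0.35 (0.0455) and Psmb8 at -0.59 (0.0439), and H2-K1 at -0.18 (0.0958) was not called. IFN-gamma-type genes had 1 rise (Irgm1 at 0.39, 0.0295) and 2 falls (Irf1 at -0.46, 0.0252, and Irf8 at -0.33, 0.0409), and a median of 0.09 beside a mean of -0.01. After the correction Irgm1 at 0.21 (0.222), Irf1 at -0.26 (0.0717) and Irf8 at -0.27 (0.0603) were not called. In MHC class II Cd74 at -0.98 (0.0168) and H2-DMb1 at -0.70 (0.0412) fell, and they were at -0.51 (0.0407) and -0.33 (0.211) after the correction. Nucleic acid sensing had 3 rises and 6 falls, among them Unc93b1 at -0.65 (0.00907), Tmem173 (STING) at -0.51 (0.0174) and Aim2 at 0.42 (0.0237). After the correction these were at -0.21 (0.136), -0.29 (0.0771) and 0.22 (0.106), and the list had 1 rise and 2 falls. Interferon receptors and signalling had 1 rise and 3 falls, with Ifnar2 at -0.54 (0.0223), and 0 rises and 1 fall after the correction. NF-kB and inflammatory cytokines had 2 rises and 6 falls, with Ptgs2 at 0.87 and Tlr2 at 0.79 (0.00907 each) against Nlrp3 at -0.74 and Tnfaip2 at -0.71 (0.00935 each), and 2 rises and 4 falls after the correction, with Ptgs2 at 0.53 (0.0247) and Tnfaip2 at -0.39 (0.0175). Among chemokines Ccl3 at 0.43 (0.0312) rose over all genes and 0 adjusted over the list alone, and 2 rose over all genes after the correction. In alternative activation Tgfb1 at -0.59 (0.0148) and Clec10a at -0.77 (0.0300) fell. After the correction Clec10a was at -0.63 (0.0577), and the list again had 2 falls.

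Microglial identity, lipid and matrix genes went both ways with AF. The homeostatic microglia and LXR lists did not pass by camera (adjusted p = 0.981 each). Homeostatic microglia genes rose in 5 and fell in 4 of 15, with Hexb at 0.54 (limma adjusted p = 0.0129) against Csf1r at -0.62 (0.00858) and Trem2 at -0.88 (0.0135). Disease-associated genes rose in 5 and fell in 4 of 19, with Spp1 (osteopontin) at 0.93 (0.00740) against Lgals3 at -1.19 (0.0108) and Clec7a at -1.37 (0.0129), and their median of -0.05 and mean of -0.19 stood beside a camera direction upwards (0.981). TGF-beta and matrix genes rose in 4 and fell in 1 of 6, with Skil, Plau and Serpine1 at 0.89 (0.00954) against Timp2 at -1.03 (0.00343), a camera adjusted p of 0.272 and a fry adjusted p of 0.000588. Cholesterol synthesis had 8 rises and 3 falls, 11 and 3 adjusted over the list alone, led by Idi1 at 0.93 (0.00783) and Hsd17b7 at 0.85 (0.0132), with a camera adjusted p of 0.0829 and a fry adjusted p of 0.00766. After the GC and length correction it had 5 rises and 0 falls, 9 and 0 adjusted over the list alone, and a camera adjusted p of 0.0167, or 0.371 with an estimated correlation. The fry test asks whether the genes of a list move 1 way on balance and compares them with no other genes. LXR targets had 2 rises and 1 fall (Nr1h3 at -0.78, 0.0227), and a median of 0.08 beside a mean of -0.02. After the correction Nr1h3 was at -0.34 (0.244), and the list had 3 rises, 0 falls and a median of 0.23. Of the 12 mitochondrially encoded transcripts 6 rose over all genes and 9 adjusted over the list alone, with mt-Nd4l at 1.17 (0.0136). Their camera adjusted p was 0.00588, or 0.741 with an estimated correlation. After the correction 1 rose, over all genes and adjusted over the list alone alike. The median was then 0.45, with 11 of 12 higher and a camera adjusted p of 0.0167, or 0.599 with an estimated correlation. Homeostatic genes then had 2 rises and 2 falls, with Csf1r at -0.39 (0.0310), and disease-associated genes 5 and 5, with Lgals3 at -0.79 (0.0124). Erythroid markers had 2 rises among 3 tested (camera 0.00588, or 0.329 with an estimated correlation). Of 87 ribosomal protein genes 12 rose and 36 fell.

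With AF, NRF2 targets had 3 rises and 2 falls (Me1 at 0.66, limma adjusted p = 0.00882, and Ftl1 at -0.94, 0.0136), and ATF4 and unfolded protein response genes 3 rises and 4 falls (Asns at 0.43, 0.0170). After the GC and length correction these were 4 rises and 1 fall of NRF2 targets and 3 rises and 0 falls of ATF4 genes. Before the correction the camera adjusted p was 0.807 for NRF2 targets and 0.981 for ATF4 genes. It was 0.324 for hypoxia and glycolysis and for the granzyme and serpin list, 0.872 for p53 targets and 0.814 for coagulation and complement. For cell cycle genes and glucocorticoid targets it was 0.981 each, so none of these lists passed. Hypoxia and glycolysis genes had 2 rises and 7 falls, with Bnip3 at 0.57 (0.0168) against Ndrg1 at -0.68 (0.0135) and Aldoa at -0.83 (0.0177), and 3 rises and 3 falls after the correction. Cell cycle genes had 5 rises and 4 falls (Bub1 at 0.63, 0.0176, and E2f1 at -0.49, 0.0204), with a median of -0.08 and a mean of 0.02. After the correction Bub1 was at 0.33 (0.0385), E2f1 at -0.05 (0.664) and the list had 3 rises and 0 falls. In p53 targets Cdkn1a at 0.55 (0.00935) and Mdm2 at 0.51 (0.0141) were among 4 rises, and Bbc3 at -0.73 (0.0135) among 3 falls, with Bbc3 at -0.12 (0.397), 2 rises and 1 fall after the correction. Glucocorticoid targets had 1 rise (Sgk1 at 0.48, 0.0193) and 1 fall (Cebpd at -1.14, 0.00935). The thrombin receptor gene F2r at 0.75 (0.00858) and Serpinb9 at 0.64 (0.0196) were the 2 rises of the granzyme and serpin list, and F7 at -0.49 (0.0196) was the fall of coagulation and complement. After the correction F7 was at -0.09 (0.365) in a list with 1 rise and 0 falls, the granzyme and serpin list had 1 rise and 1 fall, and Serpinb9 at 0.42 (0.0538), Ftl1 at -0.43 (0.0742) and Aldoa at -0.41 (0.0568) were not called. The 1 tested astrocyte marker, Aldoc at -0.89 (0.0135), and the 1 tested oligodendrocyte marker, Cnp at -0.63 (0.0141, and -0.33 with 0.0368 after the correction), fell. The epithelial marker Sfn was at -0.50 (0.0860), and the fetal liver and yolk sac markers Apoa2 at -0.57 (0.0612) and Afp at -0.48 (0.0677). The list medians of IFN-gamma-type, nucleic acid sensing, alternative activation, disease-associated microglia (0.25 after quantile normalization), ATF4, cell cycle, glucocorticoid, granzyme and serpin, coagulation, epithelial and oligodendrocyte genes changed sign under at least 1 scaling or the GC and length correction. The members behind a median could differ between settings. The oligodendrocyte median went from -0.63 to 0.19 under TPM only, although no call of a named gene, Cnp included, reversed under TPM. Actb was at 0.02 (0.851), and at -0.32 (0.0487) after quantile normalization.

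AF_GZMB against Ctrl showed the effect of both additions together. Acod1 rose by 2.77 ± 0.12 (limma adjusted p = 0.000231), Stat1 by 1.34 (0.0177), Rsad2 by 1.10 (0.0124), Irf7 by 1.01 (0.0343), Oasl2 by 1.53 (0.0111), Rtp4 by 1.65 (0.0244), Parp14 by 1.14 (0.00680), Gbp3 by 1.62 (0.0124), Irgm1 by 1.14 (0.00613), Nlrc5 by 0.98 (0.00799), Erap1 by 1.16 (0.00925) and Tap1 by 1.15 (0.0111). Usp18 at 0.80 (0.0583), Ifit1 at 0.69 (0.0932) and Isg15 at 0.96 (0.161) did not pass. Id3 fell by 2.49 (0.00519), the selenium carrier gene Selenop by 1.64 (0.00137), Apoe by 1.65 (0.0467), the transcription factor gene Maf by 1.53 (0.00613), Igfbp4 by 1.45 (0.00122) and Ifitm2 by 1.38 (0.0162). Hbb-bs and Hba-a1 were at least 95.4-fold and 75.9-fold higher than the floor of 3 reads per library. Rps27rt, Rps12-ps3, Rps27 and Usmg5 (1.73, 0.000389) rose, and all 4 are uncertain because they have copies in the genome that share reads, as is Ifitm2. In all, 235 genes rose and 324 fell. Across protein-coding genes the Spearman correlation of this change with GC content was -0.578. After the GC and length correction 352 of the 559 calls (63.0%) were kept in the same direction. The fall of Apoe was called under 9 of the 20 alternatives that kept the 4 groups in 1 fit. The count was 14 without Ctrl 1, 16 without Ctrl 2, 88 without GZMB 1 or GZMB 2, 185 without AF 1, 181 without AF 2, 3152 without AF_GZMB 1 and 169 without AF_GZMB 2. Over all genes 19 type I, 7 IFN-gamma-type and 7 MHC class I genes rose, and 34, 9 and 10 adjusted over the list alone. Their camera adjusted p was 1.66e-16, 3.46e-08 and 3.26e-07, and with an estimated correlation 0.0144, 0.0465 and 0.294. Chemokines (3 rises, 0.00672, or 0.387 with an estimated correlation), TGF-beta and matrix (3 rises and 1 fall, 0.0205, or 0.294) and cholesterol synthesis (2 rises, 0.0231, or 0.294) also passed at the preset correlation, as did erythroid markers (5.62e-05, or 0.1).

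AF_GZMB against GZMB showed the effect of amniotic fluid on cells with granzyme B. Acod1 rose by 0.79 ± 0.12 (limma adjusted p = 0.0422), from 9.21 ± 0.139 to 16.6 ± 0.254 FPKM. This rise was called under only 9 of the 20 alternatives that kept the 4 groups in 1 fit. Skil rose by 1.31 (0.00568), Plau by 1.03 (0.00568), Serpine1 by 0.89 (0.0351) and Gcnt1, a mucin-type glycosyltransferase gene, by 1.39 (0.00568). Id3 fell by 2.57 (0.00568), Maf by 1.32 (0.0159), Selenop by 1.24 (0.00568), Igfbp4 by 1.21 (0.00413), Lyz2, the macrophage lysozyme gene, by 1.09 (0.0169), Ifitm2 by 1.28 (0.0351) and Ebi3 by 1.30 (0.0470). Under the same 20 alternatives the call of Serpine1 held in 9, that of Ebi3 in 7 and that of Ifitm2 in 12. The calls of Skil, Plau, Gcnt1, Id3, Selenop and Igfbp4 held in 18 each. In all, 54 genes rose and 38 fell, with 1944 at an unadjusted p under 0.05. The count was 30 without Ctrl 1, 30 without Ctrl 2, 4 without GZMB 1, 5 without GZMB 2, 27 without AF 1, 27 without AF 2, 1469 without AF_GZMB 1 and 43 without AF_GZMB 2. Of the type I genes 0 were called over all genes and 11 rose adjusted over the list alone, with Xaf1 at 0.81 (0.0869) and Irf9 at 0.60 (0.0916), and a camera adjusted p of 7.67e-08, or 0.0602 with an estimated correlation. The TGF-beta and matrix list (3 rises and 1 fall) and cholesterol synthesis (no call) had a camera adjusted p of 0.00946 each, or 0.279 and 0.290 with an estimated correlation, and erythroid markers 1.45e-06, or 0.0809.

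Between comparisons that share no library, most genes of the smaller set of calls were in the larger set. These comparisons still share the variance estimated for each gene from all samples. Their calls are therefore not independent, although the counts by chance below assume that they are. Both changes with amniotic fluid also followed GC content (Spearman correlation -0.655 for AF against Ctrl and -0.492 for AF_GZMB against GZMB). All 4 genes that rose with GZMB in medium rose with it in amniotic fluid, where 12 were called and chance gives 0.00401, although across 11979 genes, which are not independent replicates, the Pearson correlation of both changes was -0.0402. Of 54 rises with AF_GZMB against GZMB, 52 were rises with AF against Ctrl (7.92 by chance), and of 38 falls, 35 (6.35 by chance). The changes with GZMB and with AF, which share the control libraries, had a correlation of 0.436 across genes, with simulated unchanged groups at a mean of 0.498 (0.461 to 0.546 in 100 simulations). Their covariance was 0.0538 beside a simulated 0.0247. With a separate control for each the correlation was 0.200 or 0.175 and the covariance 0.0312 or 0.0265, beside an excess of 0.0292 over the simulated covariance. The simulated groups held no trend on GC content, which both changes followed (Spearman correlation -0.422 with GZMB and -0.655 with AF). The excess therefore cannot tell a response shared by both treatments from a shared trend. None of the 4 rises with GZMB was a rise with AF (0.587 by chance).

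Several genes of the question could not be followed at this depth. Gzmb itself, Ifnb1, Ifng, Ifna4 and Cxcl9 had 0 reads in all 8 libraries, which allows up to 0.268 FPKM of Ifnb1 and 0.140 FPKM of Gzmb at a floor of 3 reads per library. Over all 8 libraries Cxcl10 had 142 reads, Ccl5 73, Ifit3 68, Il1b 11, Il6 15 and Nos2 100, and these genes were below the minimum for testing. No gene was tested from the markers of T and NK cells (8 of 12 without a read), fibroblasts (2 of 8), neutrophils (6 of 9) and neurons (2 of 8).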

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

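The tests on globin reads and the correction for GC content and gene length below were chosen after the result was seen, whereas the interaction tests were set before the data were examined.

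In tests of the difference between the granzyme B effects with and without amniotic fluid, 2 gene lists passed by camera at the preset correlation. The MHC class I list was higher with the fluid (median difference 0.27, 14 of 18 members, camera adjusted p = 0.0286) and the mitochondrial list lower (-0.59, 10 of 12 members, 0.0119). With an estimated correlation the adjusted p was 0.798 for each, and no member was called by limma (1314 of all genes had an unadjusted p under 0.05, and voom called 0). The share of mitochondrial reads was 1.92% in AF_GZMB 1 and 3.15% in AF_GZMB 2, against 3.51% and 3.96% in AF. After the GC and length correction the median difference was 0.08 in the MHC class I list and -0.47 in the mitochondrial list.

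The erythroid list passed by fry (median 0.65, 2 of 3 members higher, adjusted p = 0.000128). Its tested genes had no read without the fluid, so the value restates their change between AF_GZMB and AF and tests no difference between granzyme B effects. Hbb-bs had 1.6-fold and Hba-a1 2.22-fold as much FPKM in AF_GZMB as in AF. The 4 libraries without the fluid had 0 globin reads, so they were not the source of globin reads in the others. Beyond this the 0 reads restate the pattern and were known before the test was chosen. They decide nothing further on reads exchanged between libraries. Red cell RNA carried with the fluid stays open: the red cell membrane genes Gypa and Slc4a1 had 0 reads in the 4 libraries with it, but their level in such RNA is not in these data. Alas2, which makes haem, had 6 and 6 reads in Ctrl, 14 and 17 in GZMB, 20 and 11 in AF, and 32 and 39 in AF_GZMB. A biological explanation, globin transcription in the treated BV2 cells, may hold as well and was not tested.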

How the results depend on the processing

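The alternatives voom, protein-coding genes only, and the correction for GC content and gene length were chosen after the results were seen, as was the mean of both granzyme B effects.

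Of 229 calls of named genes none reversed under the 20 alternatives that kept the 4 groups in 1 fit, but many were lost. Kept were 228 with trimmed-mean scaling, 226 with quantile normalization, 208 with TPM, 218 with voom, 183 after the GC and length correction and 133 without a filter. Without 1 library 44 were kept (Ctrl 1), 42 (Ctrl 2), 121 (GZMB 1), 123 (GZMB 2), 113 (AF 1), 72 (AF 2), 221 (AF_GZMB 1) and 191 (AF_GZMB 2). Actb, not called with AF against Ctrl, reversed to -0.32 with quantile normalization (adjusted p = 0.0487), and the cause was not tested.

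Counts moved by more than 1.5 times as follows, and the cause was not tested. Without a filter 17 genes were called for GZMB against Ctrl, 1362 for AF against Ctrl, 194 for AF_GZMB against Ctrl, 53 for AF_GZMB against GZMB and 1 for the interaction. With voom the counts were 15 (GZMB against Ctrl), 40 (AF_GZMB against AF), 1448 (AF_GZMB against Ctrl), 223 (AF_GZMB against GZMB) and 72 (mean granzyme B effect). With protein-coding genes only they were 12, 34, 1034, 198 and 62 for the same comparisons. After the GC and length correction they were 18 (GZMB against Ctrl), 1509 (AF against Ctrl), 27 (AF_GZMB against AF), 184 (AF_GZMB against GZMB) and 52 (mean effect). Without a variance trend they were 365 (AF_GZMB against Ctrl), 58 (AF_GZMB against GZMB) and 1 (interaction). A pseudocount of 0.1 gave 20 for AF_GZMB against AF and TPM gave 61 for AF_GZMB against GZMB. A minimum absolute log2 fold change of 1 gave 422 (AF against Ctrl), 112, 42 and 14 (AF_GZMB against Ctrl, against GZMB, and the mean effect). With only the 2 groups compared 0 genes were called for GZMB against Ctrl and for AF_GZMB against AF, 4 for AF_GZMB against Ctrl and 2 for AF_GZMB against GZMB. With the replicate number as a block 2 genes were called for GZMB against Ctrl and 5 for AF_GZMB against AF. The pairing check gave 6 correlations of -0.00901 to 0.184 between samples with the same replicate number. Of these 1 was over 0.1, that of AF 1 with AF_GZMB 1. With 2 samples per group the check cannot exclude a pairing, and the labels do not state whether there was any.

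With an estimated correlation the MHC class I list had a camera adjusted p of 0.0545 for GZMB against Ctrl and 0.0688 for AF_GZMB against AF. After the GC and length correction these were 0.00337 and 0.00589. The correlation of the GZMB and AF changes was 0.504 with protein-coding genes, 0.346 after the GC and length correction, and 0.200 or 0.175 with split controls.

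Leaving out 1 library gave 0 to 5 genes for GZMB against Ctrl, 12 to 4990 for AF against Ctrl, 1 to 1094 for AF_GZMB against AF, 14 to 3152 for AF_GZMB against Ctrl, 4 to 1469 for AF_GZMB against GZMB, 0 to 622 for the interaction and 4 to 91 for the mean effect. The sample left alone in its group was assumed to vary like the other groups. The camera adjusted p ranged from 3.48e-20 to 1.11e-13 (type I), 7.25e-20 to 5.79e-13 (IFN-gamma-type) and 4.81e-28 to 5.88e-20 (MHC class I) for GZMB against Ctrl, and from 6.51e-16 to 1.29e-06, 1.91e-17 to 7.81e-07 and 1.05e-29 to 3.55e-15 for AF_GZMB against AF. The correlation of the GZMB and AF changes ranged from 0.359 to 0.537. A planned test for counts was not run, because the values were FPKM. At this depth a gene of 750 bases without a read, such as Ifnb1, is limited to 0.268 FPKM.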

Other observations

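The mean of both granzyme B effects, the correction for GC content and gene length, the SE of the list difference and the restriction to splits balanced over the fluid were chosen after the results were seen.

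Granzyme B also raised genes that no list held, and those named here were chosen after their values were seen. In the mean of both granzyme B effects (n = 4 against 4), Mpeg1, which encodes the pore-forming protein perforin-2 of macrophages, rose by 0.76 ± 0.09 (limma adjusted p = 0.0262). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose by 0.78 ± 0.09 (0.0307), Slc15a3, a transporter of bacterial peptides in lysosomes, by 0.58 ± 0.05 (0.0116), and Rgcc, a cell cycle regulator, by 0.59 ± 0.08 (0.0435). Without 1 library the count of called genes in this comparison was 4 (GZMB 1) to 91 (AF_GZMB 2).

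The genes changed with amniotic fluid followed GC content. Read depth did not separate AF from Ctrl, as the lowest total (14692200, AF 1) and the highest (16481600, AF 2) were both in AF. After thinning to the smallest library 95.8% of the 3759 genes were called in the same direction. With totals this close, thinning could change little, so that share decides little by itself. A bias of GC content and length between libraries may explain part of them, since 30.9% of the calls were kept in the same direction after the correction. That share is close to the bound set for that test. Some calls ended although their changes stayed large, so the share of lost calls does not measure the size of that part. The correction also removes real effects that follow GC content. A biological explanation, the effect of the fluid itself, is confounded with the libraries and stays open as untested.

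In a pattern noticed in these data, type I genes were moved less by granzyme B than IFN-gamma-type genes, with mean changes of 0.40 and 1.01 over both backgrounds. The means cover 41 of 53 type I and 11 of 23 IFN-gamma-type genes, those that passed the FPKM minimum. Gbp2 passed it only through the samples with granzyme B (1.78 to 2.91 FPKM, against 0 to 0.262 without it). A mean over such genes is raised by the filter, and by how much was not tested. Without Acod1 and Irf1, which left 9 IFN-gamma-type genes, the difference between the means fell from 0.60 to 0.42 (pseudocount of 1). A pseudocount hiding the changes of low genes was argued against: the difference was 0.60 with a pseudocount of 1, 0.73 with 0.5 and 0.96 with 0.1 (SE 0.08 from the spread within the 4 groups), so it widened where it should have closed. Exchanging samples within the fluid groups cannot give a p under 0.0556, so permutations decide nothing here. A candidate explanation is a signal closer to IFN-gamma than to IFN-beta, which was not tested, and both Ifng and Ifnb1 had 0 reads. All 11 tested IFN-gamma-type genes were higher with GZMB against Ctrl, but Irf8 only by 0.04 and Cd274 by 0.25. Of the untested members, Cxcl9 had 0 reads and Ciita 6 over all 8 libraries. The MHC class II list had a camera adjusted p of 0.125 for GZMB against Ctrl. For the mean effect it was 0.00339, or 0.289 with an estimated correlation.

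For the mean granzyme B effect, the real split of the 8 samples gave 32 genes with amniotic fluid as a term, and the highest of the other splits gave 1. Only splits with 2 fluid samples on each side compare like with like, and these 18 are too few for a share under 0.05. The split by amniotic fluid could not be fitted with that term.

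The AF_GZMB samples lay at 0.382 and 0.843 on an axis with Ctrl at 0 and AF at 1, and GZMB at 0.219 and 0.212. The mean positions of Ctrl and AF hold by construction. The Ctrl samples enter both the axis and the positions, so unchanged samples would tend to lie above 0 as well. Acod1 was at 16.8 and 16.4 FPKM in AF_GZMB 1 and 2, and the globin reads at 556 and 562.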
